A study of Homo sapiens with 9 samples.

How the data were processed

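RNA abundance was measured by bulk RNA sequencing in 9 libraries of DLD1, a human colorectal adenocarcinoma cell line with truncated APC. Total RNA was isolated with RNeasy columns from adherent cultures, and paired-end sequencing was used. Cells carried Cas9 with a non-targeting guide RNA (NTC, 3 libraries), a first guide against KMT2A (KO-1, 3 libraries) or a second guide against KMT2A (KO-2, 3 libraries). KMT2A encodes a histone H3 lysine methyltransferase. The labels name no other factor, and every library was assigned to its group from its own title. They do not say whether the triplicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

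The authors deposited raw counts per gene, 1 column per library, for 58735 Ensembl genes. According to the submitters' processing notes, reads were aligned with STAR 2.5.2 to hg38 and counted with featureCounts and Subread 1.6.3. The strand setting and the treatment of reads shared between genes are not stated in the sources used here, and the counts of overlapping or near-identical genes depend on them. The values were checked to be whole numbers. All 58735 identifiers matched GENCODE release 29, from which coordinates, exons and gene overlaps were taken, and 24695 genes had no count in any library. Total counts ranged from 19048843 to 19983316 per library, and mitochondrially encoded genes took between 4.13% and 4.78% of them.

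Counts were analysed in R 4.3.3 with edgeR 4.0.16. The filterByExpr function, applied by group with a minimum count of 10, left 14879 genes, and library sizes were scaled by TMM. A quasi-likelihood negative binomial model with 1 coefficient per group was fitted to all 9 libraries, so that the groups shared 1 estimate of the spread. The common biological coefficient of variation was 2.39%. Contrasts compared KO-1 with NTC, KO-2 with NTC, the mean of both guides with NTC, and KO-2 with KO-1. P-values were adjusted by the Benjamini-Hochberg method over the 14879 genes within each contrast, with a threshold of 0.05, and tests were two-sided. Levels are CPM, counts scaled to the TMM-adjusted library size, given as mean ± SD with n = 3 per group. The spread between libraries of a group, as chi-square per degree of freedom over genes, was 1.32 to 2.80, against 5.50 to 28.6 between groups, where 1 would be counting error alone.

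Because both guides were compared with the same 3 NTC libraries, errors of the controls are shared between the 2 comparisons. Groups with no change that share controls were therefore simulated 20 times, and the covariance of the log2 fold changes and the overlap of calls were set beside those simulations. They were drawn with the spread between libraries of a group, so they hold no difference between cell populations. Counts with known changes were also simulated in 3 runs. With 1.25-fold changes the test recovered 60.7% of changed genes for KO-1 against NTC and 64.7% for KO-2 against NTC, and with 2-fold changes 82.7% and 84.7%. At most 14 of 14497 genes were false calls in any run.

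A total of 29 gene lists were fixed before the data were examined, as were the tests of the comparisons, the rule for named genes and the alternatives. They cover Wnt/beta-catenin targets and pathway components, intestinal stem, enterocyte and colonocyte, and goblet and other secretory markers, HOX genes, other KMT2A and menin targets, KMT2 complexes, cell cycle, stress, signalling and metabolic groups, and markers of other cell types. The 26 lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation, with adjustment over the lists. The fry test, which asks whether members change at all and does not compare a list with other genes, was run beside it. It gave a mixed adjusted p below the threshold for all 26 lists in the mean contrast.

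Genes were named by rule. They were KMT2A, the 12 largest rises and 12 largest falls called with both guides with mean CPM of at least 5 and all 6 KMT2A libraries on the same side of all NTC libraries, and up to 4 members of each list called with both guides. Where a list had no such member, up to 2 with the smallest p were taken. AXIN2, LGR5, ASCL2, SOX9 and MYC were always included. The 8 most higher and 8 most lower genes of KO-2 against KO-1, and up to 8 genes called with 1 guide alone, completed the rule. Some genes taken by the rule are not reported here. Other genes are named with the remark that they were chosen after their values were seen. Alternatives were RLE scaling, DESeq2 1.42.0, no low-count filter, a filter on CPM of 1 in at least 3 libraries, a test against a 1.5-fold change, the replicate number as a block, the 6 libraries of a comparison alone, an estimated list correlation, and leaving out each library. Guides were matched to the annotated transcripts. Protein, histone methylation and editing rates were not analysed here.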

Results

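The transcriptome of DLD1 colorectal cancer cells was measured in 3 groups of 3 libraries, which carried a non-targeting control guide (NTC) or either of 2 guides against KMT2A (KO-1 and KO-2). Each library held between 19048843 and 19983316 counts. In the series title the experiment belongs to a genome-scale CRISPR screen of Wnt/beta-catenin signalling, and the comparisons ask which genes differ when KMT2A, a histone H3 lysine methyltransferase, is targeted. On the first principal component, which held 52.9% of the variance, the NTC libraries lay between -28.8 and -28.3, the KO-1 libraries between 5.3 and 5.9 and the KO-2 libraries between 22.6 and 23.1.

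KMT2A mRNA (ENSG00000118058, hg38 chromosome 11, 118436464 to 118526832, plus strand) fell with both guides. Its level was 114.8 ± 5.17 CPM (SD, n = 3) in NTC, 54.7 ± 1.15 CPM (n = 3) with KO-1 and 51.7 ± 3.95 CPM (n = 3) with KO-2. The log2 fold change against NTC was -1.07 (SE 0.04, edgeR adjusted p = 4.0e-23) with KO-1 and -1.15 (SE 0.04, edgeR adjusted p = 9.8e-25) with KO-2, and all 6 KMT2A libraries lay below all 3 NTC libraries. The levels with the 2 guides did not differ past the threshold (log2 fold change of KO-2 against KO-1 -0.08, SE 0.05, edgeR adjusted p = 0.28). The KO-1 guide, TACCTGCAGAAGCAAGCTAA, matches chromosome 11 from 118480217 to 118480236 on the plus strand, in coding sequence of exon 6 of the 36 exons of transcript ENST00000534358, and ends 2 bases before the end of that exon. The KO-2 guide, TCAGAGTGCGAAGTCCCACA, matches 118468812 to 118468831 on the plus strand, in coding sequence of exon 2 of the same transcript, and is followed by AGG. The NTC guide, ACAACTTTACCGACCGCGCC, matched 0 annotated transcripts. An annotated gene on the same strand, AP001267.5, shares 5599 exonic bases with KMT2A and had at most 1 count in any library, so the KMT2A count may leave out or hold reads of the shared part. The mRNA level does not measure the protein or the share of edited cells.

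**Figure D1:**
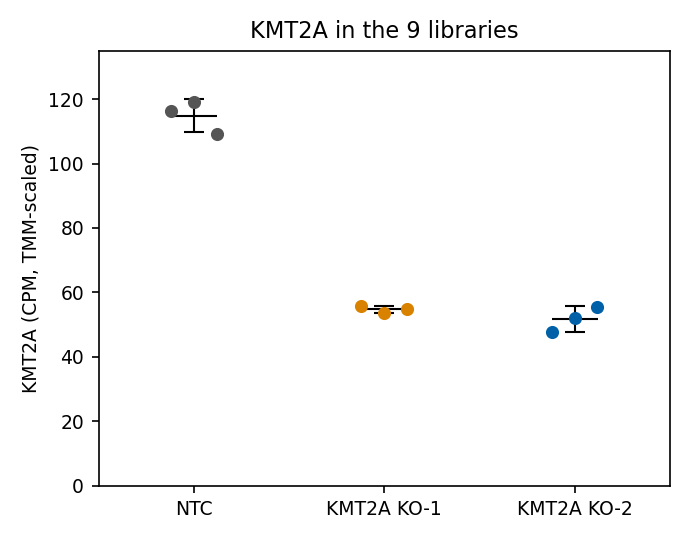
KMT2A level in TMM-scaled CPM (vertical axis) in the 9 libraries, by group, with a point per library and the mean ± SD (n = 3 each). All KO-1 and KO-2 libraries lie between 47.6 and 55.8 CPM, below the NTC libraries at 109.1 to 119.2 CPM.

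Among genes with a mean of at least 5 CPM, the largest rise with both guides was that of ZBED2, a zinc finger transcription factor, from 0.692 ± 0.144 CPM in NTC to 9.33 ± 0.729 CPM with KO-1 and 22.1 ± 1.2 CPM with KO-2 (n = 3 each). The largest fall was that of CLDN2, a pore-forming claudin of tight junctions, from 59.8 ± 2.30 to 15.3 ± 0.684 and 4.37 ± 0.505 CPM. Log2 fold changes against NTC are given with KO-1 before KO-2. Among genes that rose were the keratin-associated KRTAP2-3 (2.68 and 3.37) and KRTAP3-1 (2.53 and 3.30), the arginine deiminase PADI1 (2.10 and 2.80), the calcium-binding S100A4 (2.06 and 2.78), the microtubule-binding MAP1B (1.99 and 2.76), the collagen-binding integrin subunit ITGA1 (1.87 and 2.64) and the desmosomal cadherin DSC2 (1.67 and 2.55). The nesprin SYNE3 (1.69 and 2.31), the receptor ADGRF1 (1.81 and 2.09), C6orf15 (8.76, 26.6 and 39.0 CPM in NTC, KO-1 and KO-2) and the galectin LGALS1 (3.69, 11.2 and 15.3 CPM) rose as well. Genes that fell included the chloride channel CFTR (-1.72 and -2.82), the cytokine IL33 (-1.61 and -2.39), the secreted lectin REG4 (-1.43 and -2.41), the carbonic anhydrase CA12 (-1.37 and -2.43) and the transcription factor NFIA (-1.33 and -2.37). The chemokine CXCL5 fell from 918 ± 7.26 to 354 ± 1.03 and 221 ± 4.67 CPM, and the brush-border peptidase DPP4 (-1.38 and -2.01), RASGRF2 (-1.25 and -1.73), the nesprin SYNE1 (-1.29 and -1.54) and the noncoding CASC19 (-1.11 and -1.65) also fell. For the genes taken by this part of the rule all 6 KMT2A libraries lay on the same side of all 3 NTC libraries, the standard errors ran from 0.03 to 0.17, and the highest edgeR adjusted p was 5.2e-12.

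With KO-1, 4872 of 14879 tested genes differed from NTC at an edgeR adjusted p under 0.05 (2533 higher, 2339 lower), and with KO-2 6973 did (3498 higher, 3475 lower). Changes of at least 2-fold were fewer and mostly rises, 271 with KO-1 (211 higher, 60 lower) and 610 with KO-2 (427 higher, 183 lower). Both guides called 4369 genes in the same direction, 2263 higher and 2106 lower, where independent lists of these sizes would share 595 and 546. Among protein-coding genes 4171 of 12434 tested were called this way, so counts of members within a gene list are to be read against that share. Of the KO-1 calls, 89.7% were also called with KO-2 in the same direction, and of the KO-2 calls 62.7% with KO-1. Only SLC6A20, an amino acid transporter (-0.17 and 0.17), DYNC1H1, the dynein heavy chain (-0.14 and 0.11), and LGALS3, a galectin (0.08 and -0.14), were called in opposite directions, and these 3 were chosen after their values were seen. The mean of both guides differed from NTC for 6714 genes (3386 higher, 3328 lower). Across genes, which are not independent replicates, the log2 fold changes of the guides had a covariance of 0.131, a Pearson r of 0.874 and a Spearman rho of 0.815. In simulated groups with no change that shared controls, the covariance was 0.0116, the Pearson r 0.502 and the number of genes called with both guides 0. Against a 1.5-fold change rather than any change, edgeR called 209 genes with KO-1 (155 higher, 54 lower), 666 with KO-2 (477 higher, 189 lower) and 207 with both (153 higher, 54 lower). The 100 tested genes between KMT2A and the end of chromosome 11 differed in median log2 fold change from the rest of that chromosome by -0.05 with KO-1 and -0.10 with KO-2.

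**Figure D2:**
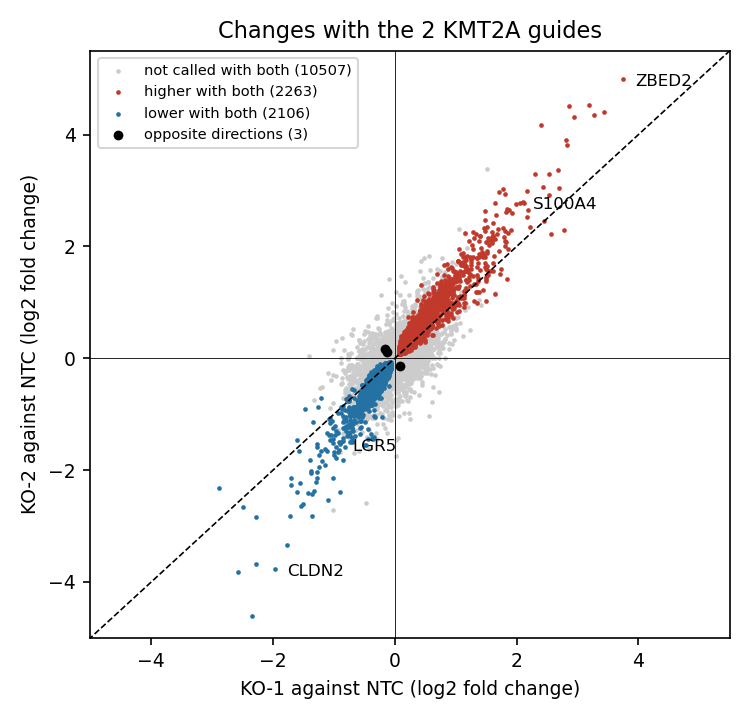
Log2 fold change against NTC with KO-1 (horizontal axis) and KO-2 (vertical axis), 1 point per tested gene, with the dashed line marking equal changes. The 2263 genes higher with both guides and the 2106 lower with both guides extend along the line, and 3800 of them changed more with KO-2.

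HOX genes, the homeobox regulators of body-axis identity and well-known targets of KMT2A, fell as a list in the mean contrast. Of 29 measured HOX genes, 11 fell with both guides, 1 rose, HOXB5 (0.30 and 0.55, named after its value was seen), and 17 were not called with both, with the same counts when adjusted over the list alone. HOXA13 went from 122 ± 2.14 CPM in NTC to 89.7 ± 2.27 with KO-1 and 44.8 ± 0.713 with KO-2 (n = 3 each), log2 fold changes of -0.44 (SE 0.03) and -1.45 (SE 0.04). HOXA10 (-0.44 and -1.27), HOXA9 (-0.32 and -1.06) and HOXA5 (-0.34 and -1.42) fell too. Of the falling genes 8 lay in the HOXA cluster, 2 among 9 measured HOXB genes and 1 among 5 HOXD genes, and none of 4 HOXC genes was called with both. The list median in the mean contrast was -0.40 (camera adjusted p = 4.19e-06, and adjusted p = 0.0144 with an estimated correlation). With an estimated correlation the list passed with KO-2 alone (camera adjusted p = 0.00839) and not with KO-1 alone (camera adjusted p = 0.0602). Several HOXA genes overlap antisense transcripts, and the strand setting of the counts is not stated. Among 14 measured KMT2A and menin targets outside the HOX clusters, 6 rose with both guides and 4 fell (6 and 4 adjusted over the list alone), with RUNX2 (0.39 and 0.49), PBX3 (0.76 and 1.37) and SIX4 (0.63 and 0.87) higher and MEF2C (-0.47 and -0.68) lower, and the list did not pass (camera adjusted p = 0.415).

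KMT2 methyltransferases and their partners held 1 member that rose and 8 that fell with both guides among 28 (2 and 8 adjusted over the list alone), KMT2A itself included. MEN1, which encodes menin (-0.26 and -0.41), and MLLT3 (-0.19 and -0.43) fell, and AFF4, a scaffold of the super elongation complex, rose (0.23 and 0.45). The list median was -0.07 (camera adjusted p = 0.0132), and the call was lost with an estimated correlation (adjusted p = 0.22) and with KO-2 alone (camera adjusted p = 0.0657).

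Direct targets of Wnt/beta-catenin signalling moved both ways. LGR5, a receptor that marks intestinal stem cells, fell from 97.1 ± 1.10 CPM in NTC to 51.9 ± 1.93 with KO-1 and 33.4 ± 0.502 with KO-2 (n = 3 each), log2 fold changes of -0.90 (SE 0.04) and -1.54 (SE 0.04). MYC, a growth regulator, fell from 204 ± 4.27 to 145 ± 2.61 and 127 ± 1.71 CPM, and ASCL2, a stem cell transcription factor, fell by 0.23 and 0.51 on the log2 scale. AXIN2, a negative feedback regulator of the pathway, rose from 274 ± 1.76 to 311 ± 6.16 and 335 ± 5.09 CPM, and SOX9 (0.23 and 0.30), the cyclin CCND1 (0.32 and 0.66) and the BMP pseudoreceptor BAMBI (0.48 and 0.80) rose. The feedback inhibitors NKD1 (0.56 and 0.89) and APCDD1 (0.58 and 0.80, from 1.72 CPM in NTC) and the transcription factor SP5 (0.50 and 0.71) rose and TDGF1 fell (-0.55 and -0.98, from 4.93 CPM), and these 4 were chosen after their values were seen. Of 22 measured targets, 7 rose with both guides, 5 fell and 10 were not called with both (7 and 6 adjusted over the list alone). The list median was 0.015 (camera adjusted p = 0.674, with the test's direction down and the median and mean above 0). The gene AC004805.1, annotated on the same strand, shares 1316 exonic bases with AXIN2.

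Wnt pathway components, from receptors to the destruction complex, had 7 members that rose and 4 that fell with both guides among 32 (7 and 4 adjusted over the list alone). The beta-catenin co-activator BCL9L (0.22 and 0.50), the receptor adaptor DVL1 (0.21 and 0.41) and the kinase GSK3B (0.13 and 0.28) rose, and the co-receptor LRP5 fell (-0.19 and -0.26). The list was not called (camera adjusted p = 0.376). Intestinal stem cell markers had 3 that rose and 5 that fell among 15 (3 and 5 adjusted over the list alone). Beside LGR5, the ephrin receptor EPHB2 fell (-0.55 and -0.66), whereas CD24 (0.45 and 0.63) and SOX9 rose (camera adjusted p = 0.0744 for the list).

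Enterocyte and colonocyte markers also moved both ways, and the secretory markers called with both guides fell. The adhesion molecule CDH17, an intestinal cadherin, fell from 164 ± 5.52 CPM in NTC to 96.2 ± 5.62 with KO-1 and 70.4 ± 2.61 with KO-2 (n = 3 each), and the mucin MUC13 (-0.84 and -1.03) and DPP4 fell. EZR, the membrane-cytoskeleton linker ezrin, rose from 910 ± 17.5 to 1214 ± 8.90 and 1512 ± 17.3 CPM. Of 16 measured enterocyte and colonocyte markers, 5 rose with both guides and 7 fell (5 and 7 adjusted over the list alone). The list was not called in the mean contrast (camera adjusted p = 0.0745), and with KO-1 alone it passed as lower (camera adjusted p = 0.0472) but not with an estimated correlation (adjusted p = 0.123). Of 12 goblet and other secretory markers, 0 rose and 3 fell (0 and 3 adjusted over the list alone), namely REG4, the trefoil peptide TFF1 (-0.83 and -1.11) and the transcription factor GFI1 (-0.49 and -0.50). The secretory list median was -0.28 (camera adjusted p = 0.0253), and the call was lost with an estimated correlation (adjusted p = 0.113).

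Targets of the YAP and TAZ co-activators rose almost throughout the list. Of 21 measured, 19 rose with both guides, 1 fell, the kinase gene NUAK2 (-0.35 and -0.29), and 1 was not called with both, MYOF (-0.03 and 0.09), with the same counts when adjusted over the list alone, and both exceptions were named after their values were seen. ANKRD1, a stretch-responsive nuclear cofactor, rose from 21.2 ± 0.904 CPM in NTC to 52.0 ± 1.45 with KO-1 and 82.6 ± 1.11 with KO-2 (n = 3 each), log2 fold changes of 1.29 and 1.96 (SE 0.05 each). The ectonucleotidase NT5E (0.73 and 1.03), the matricellular CYR61, also called CCN1 (0.61 and 0.75), and tissue factor F3 (0.49 and 0.89) rose too. The list median was 0.47 (camera adjusted p = 4.36e-25, and adjusted p = 0.00105 with an estimated correlation).

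Mesenchymal genes rose with both guides for 10 of 15 measured members and 0 fell (10 and 1 adjusted over the list alone). S100A4 went from 4.17 ± 0.191 CPM to 17.4 ± 1.10 and 28.8 ± 1.49 CPM, and the actin-binding CALD1 (0.86 and 0.95) and the matrix protein TNC (0.65 and 0.80) rose. The list median was 0.52 (camera adjusted p = 2.43e-05, and adjusted p = 0.0144 with an estimated correlation). Epithelial junction and keratin genes had 8 that rose and 3 that fell among 26 (8 and 3 adjusted over the list alone), and the keratins KRT19 (0.83 and 1.19), KRT8 (0.43 and 0.69) and KRT18 (0.27 and 0.50) rose. That list passed at a median of 0.03 (camera adjusted p = 0.00519) and was lost with an estimated correlation (adjusted p = 0.0782). KRT8, KRT18 and KRTAP2-3 have near-identical genes or pseudogenes, and the treatment of shared reads is not stated.

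Genes that report MAPK activity rose for 11 of 20 members with both guides and 1 fell (12 and 1 adjusted over the list alone). The phosphatases DUSP6 (0.51 and 0.65) and DUSP4 (1.08 and 1.86), PHLDA1 (0.38 and 0.62) and the AP-1 subunit FOSL1 (0.43 and 0.76) rose. The list median was 0.29 (camera adjusted p = 1.54e-06, and adjusted p = 0.0144 with an estimated correlation). TGF-beta and BMP response genes had 8 that rose and 2 that fell among 16 (8 and 2 adjusted over the list alone), with PMEPA1, a feedback inhibitor of TGF-beta signalling (1.20 and 1.59), and ID2 (0.44 and 0.55) higher and the ligand BMP2 lower (-0.59 and -0.89). Its median was 0.18 (camera adjusted p = 0.00974), and the call was lost with an estimated correlation (adjusted p = 0.212).

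**Figure D3:**
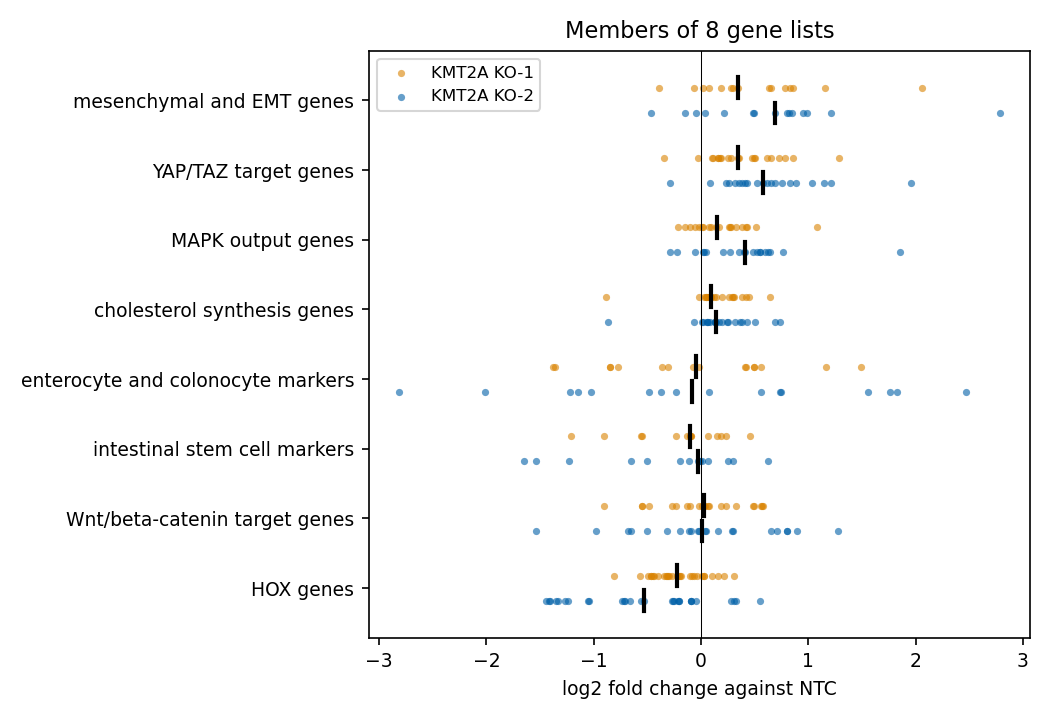
Log2 fold change against NTC (horizontal axis) of each tested member of 8 of the 29 gene lists, with KO-1 above KO-2 in each list and a black bar at the median. YAP/TAZ targets lie mostly to the right of 0 and HOX genes mostly to the left, while Wnt targets and enterocyte markers lie on both sides.

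Cholesterol synthesis genes rose for 11 of 23 members with both guides and 1 fell (12 and 1 adjusted over the list alone). The sterol sensor INSIG1 (0.64 and 0.69) and the enzymes MSMO1 (0.42 and 0.51) and FDFT1 (0.26 and 0.32) rose, at a list median of 0.11 (camera adjusted p = 2.73e-05, and adjusted p = 0.0144 with an estimated correlation). Cytosolic ribosomal protein genes fell for 31 of 68 with both guides and 0 rose (34 and 0 adjusted over the list alone), such as RPS24 (-0.10 and -0.32), RPL22 (-0.24 and -0.37) and RPL7 (-0.10 and -0.23). The ribosomal list median was -0.13 (camera adjusted p = 1.07e-07), and the call was lost with an estimated correlation (adjusted p = 0.412). Nuclear oxidative phosphorylation genes fell for 7 of 34 and 0 rose (7 and 0 adjusted over the list alone), among them NDUFB10 (-0.19 and -0.45) and ATP5F1B (-0.10 and -0.21), at a median of -0.09 (camera adjusted p = 0.0208, and adjusted p = 0.445 with an estimated correlation), and the list was not called with KO-1 alone (camera adjusted p = 0.236). Of the 13 mitochondrially encoded genes 3 fell (4 adjusted over the list alone), such as MT-ND3 (-0.22 and -0.31), and the list was not called (camera adjusted p = 0.376, with a median of 0.01 and the test's direction down).

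Hypoxia and glycolysis genes had 7 that rose and 7 that fell among 24 (7 and 7 adjusted over the list alone). The glucose transporter SLC2A1 (0.68 and 1.14) and NDRG1 (0.88 and 1.17) rose and the hexokinase HK2 fell (-0.64 and -0.98), and the list was not called (camera adjusted p = 0.173). Unfolded protein and integrated stress response genes had 7 that rose and 11 that fell among 24 (8 and 12 adjusted over the list alone). The serine synthesis enzyme PHGDH (-0.37 and -0.55) and the chaperones HSP90B1 (-0.28 and -0.38) and PDIA4 (-0.29 and -0.39) fell and the stress transcription factor ATF3 rose (0.83 and 0.91), with a camera adjusted p of 0.0745 for the list.

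Replication genes changed by small amounts. Of 30 G1/S genes, 1 rose and 9 fell with both guides (1 and 9 adjusted over the list alone), among them the helicase subunits MCM7 (-0.17 and -0.25), MCM4 (-0.16 and -0.21) and MCM2 (-0.17 and -0.24) and the transcription factor E2F2 (-0.24 and -0.57). The G1/S median was -0.08 (camera adjusted p = 0.0202, and adjusted p = 0.0908 with an estimated correlation), and the list was not called with KO-1 alone (camera adjusted p = 0.0522). Of 26 G2/M genes 1 rose and 5 fell (1 and 5 adjusted over the list alone), such as ECT2 (-0.18 and -0.23) and BIRC5 (-0.12 and -0.22), with a camera adjusted p of 0.224. Among 24 p53 targets 6 rose and 6 fell (6 and 6 adjusted over the list alone), with the kinase inhibitor CDKN1A (0.84 and 1.19) and PLK2 (0.51 and 0.75) higher and the secreted GDF15 (-0.64 and -1.14) and RPS27L (-0.36 and -0.71) lower (camera adjusted p = 0.781).

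NF-kappaB and inflammatory genes included changes in both directions. Of 21 measured members 5 rose and 6 fell with both guides (5 and 6 adjusted over the list alone), with CXCL5, SOD2 (-0.31 and -0.42) and NFKB1 (-0.26 and -0.36) lower and NFKB2 higher (0.30 and 0.41). Its mean log2 fold change was -0.10 and its median 0.01, so that median and test (camera adjusted p = 0.0185, down) differed in sign, and the call was lost with an estimated correlation (adjusted p = 0.113) and with KO-2 alone (camera adjusted p = 0.0812). Among 29 interferon-stimulated genes 5 rose and 3 fell (5 and 3 adjusted over the list alone), with OAS2 (1.56 and 1.56) and IRF1 (0.38 and 0.46) higher and IFIH1 lower (-0.33 and -0.43), and the list was not called (camera adjusted p = 0.934). Among 12 Notch pathway genes 2 rose and 3 fell (2 and 3 adjusted over the list alone), with the ligand JAG1 (-0.50 and -0.87) and NRARP (-0.48 and -0.63) lower and HES4 higher (0.34 and 0.31), with a camera adjusted p of 0.182.

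Markers of other cell types were near the floor. Of 15 leukocyte markers 3 were tested, and CSF1R rose from 0.824 ± 0.201 CPM in NTC to 2.37 ± 0.253 with KO-1 and 3.09 ± 0.388 with KO-2 (n = 3 each). Of 13 fibroblast markers 2 were tested and 0 changed, COL1A1 staying at or under 0.592 CPM on average in each group. Of 6 endothelial markers tested 0 were called with both guides (camera adjusted p = 0.769), while against NTC 2 were called higher and 1 lower with KO-2 and 0 with KO-1. Of 12 neural and embryonic kidney markers 2 were tested, and TUBB3 rose (0.60 and 0.91) from 2.27 ± 0.181 CPM. Among the untested members of these lists the highest level in any library was 0.573 CPM. In the mean contrast 13 of 26 lists were called by camera (6 up, 7 down), and 5 with an estimated correlation, namely HOX, YAP/TAZ, MAPK, mesenchymal and cholesterol synthesis genes. With KO-1 alone camera called 12 lists and with KO-2 alone 11, and with an estimated correlation 4 and 6. In the mean contrast as many lists were called in 5 of 100 splits of the 9 libraries, the real grouping included.

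The comparison of KO-2 with KO-1 asks whether the guides differ from each other. CLDN2 was lower with KO-2 than with KO-1 (log2 fold change -1.81, edgeR adjusted p = 3.7e-18), as were CFTR (-1.10), CA12 (-1.07) and NFIA (-1.04), and genes of the HOXA cluster were lower too, namely HOXA5 (-1.07) and the noncoding HOXA11-AS (-1.09) and HOTTIP (-1.04). ZBED2 was higher with KO-2 (1.24, edgeR adjusted p = 5.4e-16), together with the kallikrein KLK10 (0.89), DSC2 (0.89), the myosin MYH15 (0.87), the semaphorin SEMA7A (0.82), DUSP4 (0.78), ITGA1 (0.77) and KRTAP3-1 (0.77). In all, 2347 of 14879 genes differed between the guides (1251 higher and 1096 lower with KO-2), 64 of them by at least 2-fold. Of the 2347, 2217 (94.5%) differed in the direction of the mean change from NTC and 130 against it. Of the 4369 genes called with both guides 3800 (87%) changed more with KO-2, and 1501 were also called between the guides, 1496 larger with KO-2 and 5 larger with KO-1. DESeq2 called 1558 genes, and edgeR called 20 against a 1.5-fold change.

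All 11 tested HOXA genes were lower with KO-2 than with KO-1. The cluster spans 27092993 to 27200106 on chromosome 7, and the median log2 fold change of its HOX genes was -0.34 with KO-1, -1.27 with KO-2 and -0.84 between the guides. HOXA10 differed by -0.83 between the guides (edgeR adjusted p = 2.2e-15). The 49 tested genes within 5 Mb on either side had a median of -0.02 (95% interval -0.09 to 0.05). The HOXA genes were singled out after their values were seen.

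**Figure D4:**
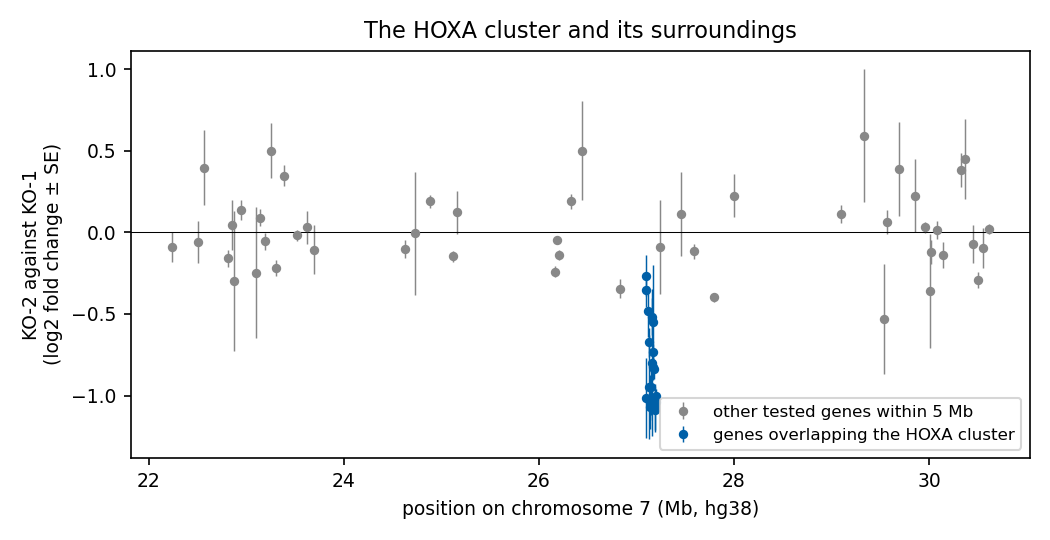
Log2 fold change of KO-2 against KO-1 ± SE (vertical axis) of tested genes by position on chromosome 7 in Mb (horizontal axis), with genes overlapping the HOXA cluster in blue and others within 5 Mb in grey. All blue points lie below 0, and the grey points lie on both sides of 0, with a median of -0.02.

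Of 26 lists, camera called 11 between the guides (6 higher and 5 lower with KO-2). HOX genes (median -0.20, adjusted p = 0.00127), YAP/TAZ targets (0.19, 0.00127), MAPK output genes (0.22, 0.00463) and epithelial junction and keratin genes (0.05, 0.0189) held with an estimated correlation, to which these camera p-values belong. The others were lost with it, at an adjusted p of 0.205 for ribosomal protein genes (median -0.12), 0.184 for oxidative phosphorylation genes (-0.11), 0.363 for mitochondrially encoded genes (-0.10), 0.0751 for mesenchymal genes (0.10), 0.184 for TGF-beta and BMP response genes (0.13), 0.0536 for G1/S genes (-0.06) and 0.363 for Wnt pathway components (0.05). The call for Wnt components was also lost without KO-1 replicate 2 (camera adjusted p = 0.104) and without KO-2 replicate 3 (camera adjusted p = 0.0645).

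Some genes were called with a single guide and differed between the guides. Log2 fold changes against NTC are again given with KO-1 before KO-2. Genes called as higher with KO-1 alone were the noncoding HOXB-AS3 (0.42 and -0.09), ACYP1 (0.40 and -0.01) and CSGALNACT1 (0.35 and 0.06). Those called as lower were MICAL3 (-0.25 and -0.06), the H3K4 methyltransferase gene KMT2D (-0.22 and 0.02), the DNA repair gene RAD50 (-0.22 and 0.06) and the proliferation marker MKI67 (-0.21 and -0.07). Levels also varied within groups. From replicate 1 to 3, KMT2D went from 119.8 to 105.7 CPM in NTC and from 106.6 to 121.5 CPM with KO-2. MKI67 was higher in KO-1 replicate 1 (796.2 CPM) than in NTC replicate 3 (787.2 CPM). RAD50 did not pass with DESeq2 (adjusted p = 0.125) or without the low-count filter (edgeR adjusted p = 0.0688). Genes called as higher with KO-2 alone were TMEM158 (0.25 and 0.67), the serpin SERPINB5 (0.20 and 0.65), the semaphorin receptor PLXNA2 (0.09 and 0.64) and ZNRF2 (0.21 and 0.59). Those called as lower were HOXA7 (-0.22 and -0.74), TP53I11 (-0.21 and -0.57), MTERF2 (-0.17 and -0.55) and TPM3P9 (-0.14 and -0.54). Their changes with KO-1 had the same sign but did not pass the threshold. In the edgeR comparison of the guides themselves the adjusted p of the genes taken by this part of the rule was at most 0.0325.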

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

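The tests of the share of edited cells, of the general difference between the guides for HOXA genes, and of windows of neighbouring genes elsewhere in the genome were chosen only after the result was seen.

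KO-2 differed from KO-1 for 2347 genes and for 11 gene lists, although both guides target KMT2A, and 3 genes (SLC6A20, LGALS3 and DYNC1H1) were called in opposite directions by the guides. These are differences between groups given the same nominal treatment. In the 10 splits of the 6 libraries of each pairwise comparison the real grouping gave 4872 genes for KO-1 against NTC, 6973 for KO-2 against NTC and 2347 for KO-2 against KO-1, the highest of the other splits gave 0 in each case, and 10 splits are too few for a share under 0.05. The same holds for the 11 lists, where the highest other split gave 8. Over 100 splits of the 9 libraries only the real grouping gave as many genes for the mean of both guides (6714, highest other 5674). The same held for genes called with both guides (4369, highest other 3774). For the covariance (0.1306, highest other 0.1372) 3 splits were as large, the real one included. These splits test only the labels of the libraries. The triplicates may be technical, so the splits cannot exclude chance differences between the cell populations. For the 13 lists called in the mean contrast 5 splits gave as many, the real one included, and the highest other gave 13, so chance was not excluded. Among these other splits were some that kept the 3 KO-2 libraries together and called 2125 to 2464 genes in that contrast. Another of them called 0 genes, so the number of called lists can be as high where no gene is called. The 2 other splits with the highest gene counts kept the 3 NTC libraries together and so reflect the structure of the samples.

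The first pattern is the 4369 genes that changed alike with both guides. A trend with GC content or gene length is argued against as the whole source, since 97.5% of these genes were still called with both guides after a correction for both. Loss of the part of chromosome 11 beyond KMT2A may add to the falls there, with the 100 distal genes -0.053 (95% interval -0.113 to -0.008) with KO-1 and -0.103 (-0.166 to -0.042) with KO-2 from the rest of the chromosome. Windows of 100 neighbouring tested genes were taken over the autosomes and X, without the distal genes. Of 136 such windows, 4 had a median as low as the distal genes with KO-1 and 0 with KO-2. A loss in some cells cannot be told apart from regulation of the distal genes. By dosage a loss would reach the distal genes only, of which 24 were lower and 13 higher with both guides. Reduced KMT2A stays an open explanation. Of the covariance of 0.1306, the spread between libraries of a group, shared through NTC, gave 0.0116 in simulation. A difference of the NTC cell population itself would enter both comparisons, is not in that simulation and was not tested.

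The second pattern is the larger change with KO-2, seen in 3800 of the 4369 genes, with a median ratio of KO-2 to KO-1 log2 fold changes of 1.354 in 265 raised and 1.594 in 87 lowered genes of at least 2-fold mean change, while KMT2A mRNA did not differ past the threshold. A copy-number difference of a whole chromosome between the 2 knockout populations is argued against, since the chromosome median farthest from 0 was -0.02. A smaller share of edited cells in the KO-1 population could give the same ratio of change in every gene, and among the 1501 shared genes also called between the guides, a choice that lowers the ratio itself, the median ratio of KO-1 to KO-2 change was 0.607 in 638 lowered and 0.537 in 863 raised genes, a difference of 0.07 against -0.01 to 0.007 in simulated mixtures. That difference lay between the bounds set for it, and the fall of mRNA per edited cell may differ by guide. For genes that changed more with KO-2, an edited share therefore cannot be told apart from a different effect of each guide. An edited share alone would put no gene against the mean change from NTC or in opposite directions. It is argued against as the source for the 130 and 3 genes so called, some of which may be false calls. A different degree of KMT2A loss or an off-target effect was not tested.

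The third pattern is the stronger fall of the HOXA cluster with KO-2. Copy loss of the surrounding part of chromosome 7 is argued against by the median of -0.019 over 49 genes within 5 Mb. The general difference between the guides stays open, because the cluster was chosen for its values, so that a median of -0.839 below all 10000 sets of matched but unlinked genes (lowest -0.63) excludes nothing. A smaller edited share in KO-1 stays open for the same reason, with a median ratio of KO-1 to KO-2 change of 0.397 over all 11 HOXA genes, 8 of them called with both guides, against 0.608 in other genes that had to be lowered with both guides and lower with KO-2 than with KO-1, where 0 of 10000 random sets were as low (lowest 0.432) although a mixture would give 1 common ratio. A regional effect on the cluster was not tested.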

How the results depend on the processing

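No test here was chosen after the result was seen. No result reversed, and of the alternatives 130 values of the main results stayed within their limits and 20 moved. Counts moved with DESeq2 for KO-2 against KO-1 (1558 genes), where 2597 genes had no adjusted p, and against a 1.5-fold change, a stricter question, to 209 (KO-1), 666 (KO-2), 446 (mean), 20 (KO-2 against KO-1) and 207 (both guides). The covariance moved to 0.1326 with DESeq2, 0.7673 with no low-count filter, where genes near 0 counts enter, and 0.1099 with CPM of 1 or more in at least 3 libraries. Leaving out each library let more genes pass the low-count filter, 15097 to 15119 against 14879. The covariance was then 0.1317 to 0.1476, and how far the added genes caused this was not tested. The spread set beside it, 0.0011, is the SD over 3 sets of 1 library per group, whose own covariances were 0.0935, 0.0916 and 0.0917. With an estimated correlation 5 lists were called in the mean contrast and 4 between the guides. Among lists that lost their call in the mean contrast, the estimate was -0.027 for secretory, -0.027 for G1/S and 0.009 for epithelial genes. These lie below the preset 0.01, so higher correlation of members does not account for those lost calls. For the others the estimate was 0.011 (NF-kappaB), 0.077 (KMT2), 0.121 (TGF-beta and BMP), 0.206 (oxidative phosphorylation) and 0.546 (ribosomal). The cause was not tested either. Without each library in turn, the counts were 4013 to 4845 (KO-1), 6246 to 7186 (KO-2), 5779 to 6780 (mean), 1627 to 2446 (KO-2 against KO-1) and 3667 to 4225 (both guides). For 5 of 9 libraries the best match in another group had the same replicate number. Correlations ran from -0.158 to 0.355 for the same number and from -0.36 to 0.207 for other numbers. Pairing by number was therefore neither shown nor excluded. With the number as a block the counts were 4985, 7064, 6805, 2481 and 4469. Of the named gene results 843 kept their status, called or not called, and 92 lost their call, 90 of these against a 1.5-fold change. Of the results for called lists 317 kept their call and 21 lost it, 15 of these with an estimated correlation. At this depth 60.7% of the smallest simulated changes were recovered for KO-1 against NTC, so small changes may be missed.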

Other observations

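The correlation of neighbouring genes was tested as set out before its result was seen, and the named genes of the first paragraphs were chosen after their values were seen.

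Within the enterocyte and colonocyte markers, members moved in both directions. With both guides the microvillus protein VIL1 (-0.85 with KO-1 and -1.14 with KO-2) and the transcription factors CDX2 (-0.31 and -0.49) and HNF4A (-0.36 and -0.37) fell, while CEACAM6 (1.49 and 2.47), CEACAM1 (1.17 and 1.76) and the keratin KRT20 (0.49 and 0.56) rose. Among stem cell markers PROM1 fell (-1.21 and -1.65), as did TERT, the telomerase catalytic subunit (-0.56 and -1.23), while the Polycomb gene BMI1 rose (0.19 and 0.25). Among mesenchymal genes VIM (1.16 and 0.98), ZEB1 (0.64 and 0.82) and AXL (0.78 and 1.21) rose, while the epithelial cadherin CDH1 was not called with both guides (-0.03 and 0.10).

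Among inflammatory genes the chemokines CXCL3 (-1.15 and -1.63) and CXCL8 (-0.75 and -0.89) fell while SAA1 rose (1.22 and 2.09). CEACAM6, CEACAM1, PROM1, TERT, VIM, ZEB1, AXL, CXCL3, CXCL8 and SAA1 each had a mean below 5 CPM in NTC, and the standard errors of their log2 fold changes ran from 0.15 to 0.30.

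Adjacent genes may change together because they lie in shared chromatin domains. Over 10022 pairs of neighbouring tested genes the mean changes had a correlation across genes of 0.12, against at most 0.033 in 1000 shuffles, just above the bound of 0.1 set for this hypothesis. It was 0.12 after correction for GC content and length, 0.118 without the HOXA cluster, 0.061 for KO-2 against KO-1 and -0.011 for the difference of NTC replicates 1 and 2. Those 2 replicates differed by little more than counting error (chi-square per degree of freedom 1.32), so their difference could hardly show such a relation. The relation is small, and shared domains were not measured.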
